A study of Mus musculus with 6 samples.

How the data were processed

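Gene expression was measured in whole corneas of mouse pups at postnatal day 3 on Affymetrix Mouse Gene 1.0 ST arrays, which carry probes along the length of each transcript. There were 3 arrays of wild-type (WT) corneas and 3 of corneas from littermates carrying a dominant-negative CLIM transgene (DN-Clim) under the keratin 14 promoter. CLIM proteins are cofactors that bind LIM-domain transcription regulators. Per the labels' protocols, corneas were freed of other eye tissue, RNA was checked by PCR for markers of adjacent tissues, and cDNA was amplified with a NuGEN kit before labelling with biotin. The labels do not say whether a replicate was 1 animal or a pool, so p-values measure the spread between these samples, which may be partly technical.

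The deposited values were probe set intensities on a linear scale. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.1 and PLIER, a model that combines the probes of a probe set. The background correction, the normalization between arrays and any offset are not given in the sources used here. The deposited table held 35557 probe sets. Median intensities ran from 230.8 in DN-Clim replicate 2 to 280.9 in DN-Clim replicate 3, and between 2.26% and 3.23% of the values of an array lay below 16. The number of arrays limits the precision.

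Intensities were taken as log2(intensity + 16), so that fold changes of dim genes are understated. Array medians on this scale differed by at most 0.267, below the 0.5 set for centring, and no further normalization was applied. A platform table paired 23410 probe sets with at least 1 gene. Of these, 21789 had exactly 1 symbol (19938 distinct symbols) and 1621 had several, and no gene is named from the latter. The other 12147 probe sets are unnamed here and were not tested. The 23410 probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), DN-Clim minus WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for genes come from limma. With 200 probe sets changed in data simulated for 3 DN-Clim against 3 WT over the 23410 probe sets, the fit recovered 30% of those changed 2-fold, 86% at 4-fold and 96% at 8-fold, with 8 false calls. The simulated noise was independent between probe sets and arrays. These figures therefore leave out structure that many genes share on the real arrays, such as the lens signal described below.

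Gene lists for corneal cell types, neighbouring eye tissues, signalling pathways and technical classes, 42 in all, were fixed before the data were examined, and 8 members were matched through a newer or older symbol. Each of 41 lists was tested with limma's camera on 1 probe set per gene, the one with the highest mean, with a preset correlation between genes of 0.01 and adjustment over the 41 lists. Sex-linked genes were only described. Camera compares a list with all other genes. The tests were repeated with a correlation estimated from the data and with fry, which asks whether the genes of a list move one way, and in its mixed form whether they move in either direction. A member was said to rise or fall only if it passed the adjusted threshold over all probe sets.

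The genes named were fixed by a rule beforehand. Ldb1, Ldb2, Krt14, Krt12, Pax6, Krt5, Col17a1, Axin2, Lef1 and Lmo4 were always named. The 12 largest increases and the 12 largest decreases past the threshold with no overlap between the groups were added, and free places went to genes with an unadjusted p under 0.01 and no overlap, described as not passing. For a described list, up to 4 passing members were taken, or 2 with the smallest p where none passed. Predicted loci and olfactory receptors were skipped. For a gene with several probe sets, the one with the largest change is given under the rule of largest changes. The same rule was applied to the fit without DN-Clim replicate 3.

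Alternatives were other offsets, quantile normalization, median centring, filters on dim probe sets, all probe sets of the table, a trended robust prior, array weights, the replicate number as a block, a sex covariate from Xist and Y-linked genes, and leaving out each array. After the data were examined, a fit of DN-Clim replicate 3 alone against WT and a fit with the mean lens signal as a covariate were added.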

Results

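Whole-cornea RNA of pups at postnatal day 3 was profiled in 6 samples, 3 from WT mice and 3 from DN-Clim littermates, in which a dominant-negative form of the CLIM cofactors is driven by the keratin 14 promoter in basal epithelial cells. The comparison asks which corneal genes depend on CLIM function, and the study's title names Wnt signalling and epithelial stem cells as its subject. Values below are log2 intensities, and differences are DN-Clim minus WT. The arrays did not separate by group alone. DN-Clim replicate 3 correlated with the WT arrays at 0.949 to 0.962, and with DN-Clim replicates 1 and 2 at 0.928 and 0.900. The WT arrays correlated with each other at 0.970 to 0.981. DN-Clim replicate 1 correlated at 0.964 with DN-Clim replicate 2 and at 0.965 with WT replicate 3.

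With all 6 arrays, 3 genes fell in the DN-Clim corneas and none rose past the adjusted threshold. Emcn, a sialomucin of capillary and venous endothelium, went from 9.90 ± 0.21 (SD, n = 3) in WT to 7.46 ± 0.20 (SD, n = 3), a difference of -2.44 (SE 0.198, limma adjusted p = 0.0113). Ctla2a, a cysteine protease inhibitor, differed by -1.91 (SE 0.193, adjusted p = 0.0248). Psca, a glycolipid-anchored surface protein of epithelia, differed by -1.87 (SE 0.178, adjusted p = 0.023). All 3 DN-Clim arrays lay below all 3 WT arrays for each of these genes. Leaving out DN-Clim replicate 3 raised the count to 483 probe sets, and leaving out any of the other 5 arrays lowered it to 0, with smallest adjusted p-values between 0.0539 and 0.195.

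At an unadjusted p under 0.05 there were 1390 probe sets, against 1170.5 expected by chance, of which 1050 were lower and 340 higher in DN-Clim. The groups did not overlap for 10.1% of probe sets, where chance gives 10%. Among genes that did not pass but had an unadjusted p under 0.01, the largest non-overlapping decrease was in Tnmd, a tendon and ligament glycoprotein (-2.36, adjusted p = 0.411). The serine protease homologue Prss35 differed by -2.34 (adjusted p = 0.0597), and the endothelial lectin Clec14a by -1.93 (adjusted p = 0.0628). Aspn, Hmcn1, Mfap5, Lama4 and Ecm2, all of the extracellular matrix, differed by between -2.28 and -1.90, and Nlrc5, a regulator of MHC class I genes, by -2.12. Under the same limit of 0.01 the largest non-overlapping increases, none of which passed, were in Pgam2, a muscle form of phosphoglycerate mutase (1.97, adjusted p = 0.512), and in Mylpf, a fast-muscle myosin light chain (1.68, adjusted p = 0.622). They also included Tmprss11d, Kbtbd11, Aldh1a1, Akr1e1, Rtkn2, Srrm4, Riiad1, Cryab, Dnajc6 and Gucy1a2, with differences from 0.88 to 1.51.

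**Figure D1:**
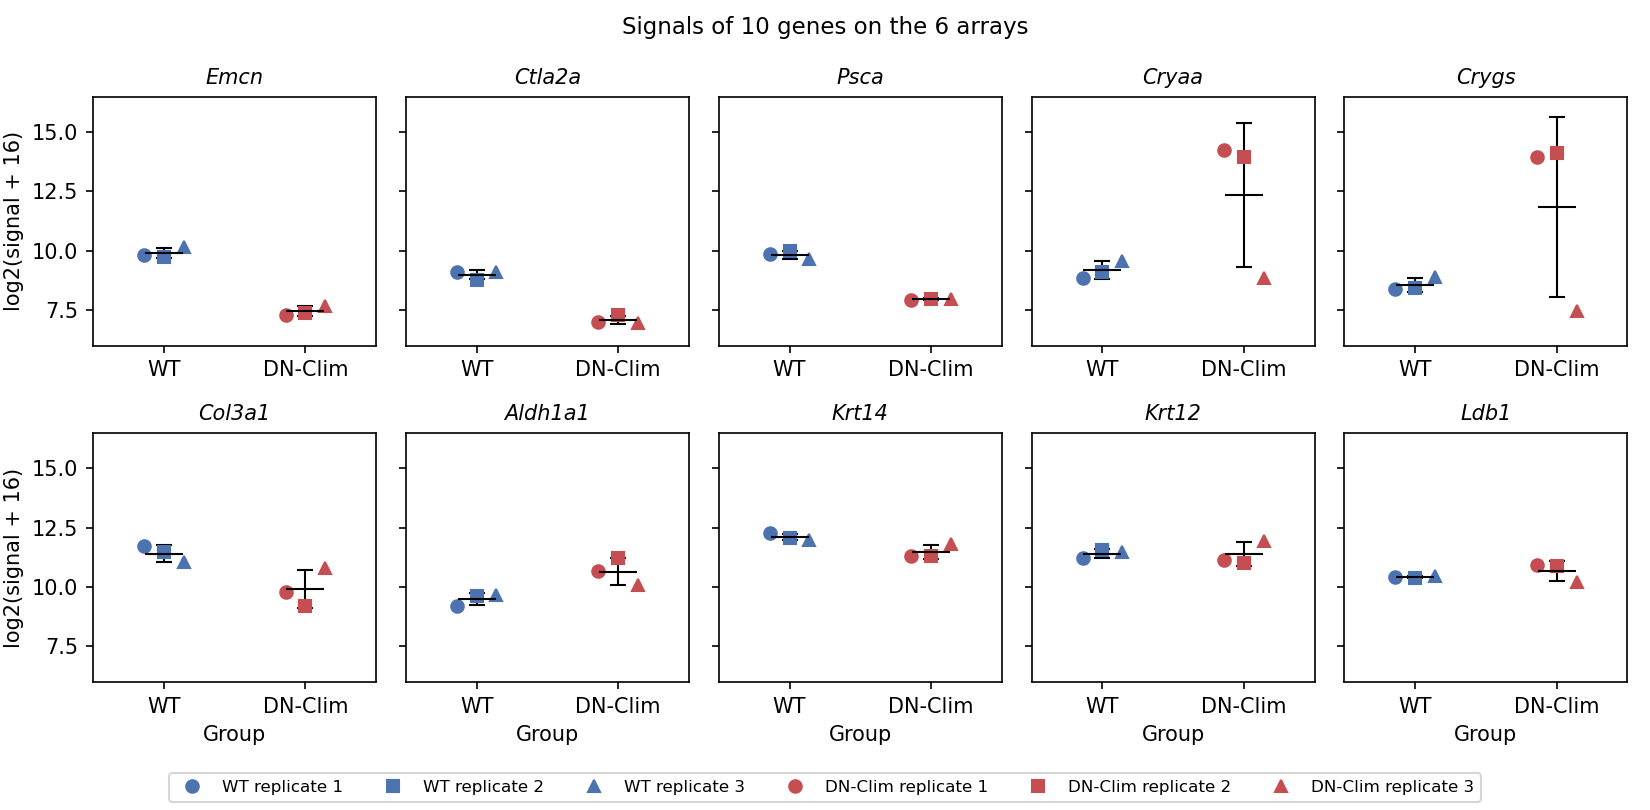
Each panel plots log2(signal + 16) of 1 gene on the 3 WT and 3 DN-Clim arrays, with points for arrays, bars for the mean and whiskers for the SD. Emcn, Ctla2a and Psca are lower on all 3 DN-Clim arrays, whereas Cryaa and Crygs are high on DN-Clim replicates 1 and 2 only.

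The genes that bear on the transgene did not differ past the threshold with all arrays. Ldb1, which encodes a CLIM protein, read 10.42, 10.37 and 10.46 in WT and 10.94, 10.89 and 10.22 in DN-Clim replicates 1, 2 and 3. Ldb2, the other CLIM gene, read 8.84, 9.17 and 9.36 in WT and 9.81, 9.25 and 8.54 in DN-Clim. The sources used here do not say which part of a CLIM gene the transgene carries, so neither gene checks the labels. Krt14, a keratin of basal epithelium whose promoter drives the transgene, read 12.26, 12.08 and 11.99 in WT and 11.30, 11.31 and 11.83 in DN-Clim. The Krt14 difference was -0.63 (adjusted p = 0.721).

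Of the epithelial, Wnt and LIM genes always named, none passed with all arrays. Krt12, the keratin of differentiated corneal epithelium, differed by -0.03 (SE 0.26), and Pax6, the eye transcription factor, by 0.19 (SE 0.171). Krt5, the partner of Krt14, differed by -0.31 (SE 0.173), and Col17a1, a hemidesmosome collagen, by -0.22 (SE 0.266). Axin2 and Lef1, which respond to Wnt, differed by -0.04 (SE 0.19) and -0.23 (SE 0.208), and Lmo4, a LIM-only partner of CLIM, by -0.37 (SE 0.201). Their adjusted p-values ran from 0.929 to 0.999. The Axin2 sign turned with quantile normalization and median centring, the Krt12 sign with median centring, and the signs of Krt12, Col17a1, Axin2 and Ldb2 when single DN-Clim arrays were left out. The Krt12 sign also turned without WT replicate 2 and without WT replicate 3, and the Ldb2 sign without WT replicate 1.

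As gene lists, 22 of 41 passed the camera threshold, 7 higher and 15 lower in DN-Clim. None of the 22 passed with an estimated correlation and none with the directional fry test. In fry's mixed test, which allows members to move either way, 2 of the 41 passed, vascular endothelium (adjusted p = 0.00698) and macrophages (adjusted p = 0.0172). The vascular endothelium list was lower, with a median difference of -0.43 over 18 genes (camera adjusted p = 1.74e-08, and 0.342 with an estimated correlation). Emcn was the member that fell, and 5 fell adjusted over the list alone. On DN-Clim replicates 1, 2 and 3 the list medians relative to the WT mean were -0.50, -0.56 and -0.16. The macrophage and myeloid list was lower, with all 23 members below 0 and a median of -0.30 (adjusted p = 3.63e-08, and 0.342 with an estimated correlation). No member passed over all genes and 1 fell adjusted over the list alone. Mrc1, a mannose receptor of macrophages, differed by -1.46, and Lyz2, a lysozyme, by -0.79. The array medians were -0.32, -0.41 and -0.26. The fibrosis and myofibroblast list had a median of -0.65 over 21 genes (adjusted p = 7.16e-08, and 0.342 with an estimated correlation). None of its members passed and 5 fell adjusted over the list alone. Acta2, smooth muscle actin, differed by -1.45 and Cnn1, calponin, by -0.94. The array medians were -0.46, -1.16 and -0.19, so that the decrease was mostly on the arrays with the lens signal given below.

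The keratocyte and stromal matrix list was the one with the largest negative median, -0.77 over 28 genes, 26 of them below 0 (adjusted p = 1.72e-11, and 0.342 with an estimated correlation). None passed over all genes. Adjusted over the list alone, 1 rose and 1 fell. Col3a1, a fibrillar collagen, differed by -1.48, and Aldh1a1, a retinaldehyde dehydrogenase abundant in keratocytes, by 1.15. The list medians of the DN-Clim arrays, relative to the WT mean, were -0.96, -1.36 and -0.04 in replicates 1, 2 and 3, and the list lost its call with replicate 3 alone against WT.

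Epithelial lists were also lower, with smaller medians. The hemidesmosome and basement membrane list had a median of -0.26 over 24 genes (adjusted p = 2.98e-05, and 0.525 with an estimated correlation), with 0 members past the threshold and 1 fallen adjusted over the list alone. Cd151, a tetraspanin of hemidesmosomes, differed by -0.88 and Nid1, nidogen, by -1.15. On DN-Clim replicates 1, 2 and 3 the list medians relative to the WT mean were -0.21, -0.66 and 0.08. The corneal epithelial differentiation list had a median of -0.36 over 19 genes (adjusted p = 5.17e-05, and 0.508 with an estimated correlation), and 0 members passed, also adjusted over the list alone. Aldh3a1, an abundant corneal aldehyde dehydrogenase, differed by -1.09 and Foxc1 by -0.70. Its array medians were -0.26, -0.69 and -0.03. Replicates 1 and 2 are those with the lens signal given below. Both lists lost the call with the sex covariate, with the lens covariate and with replicate 3 alone, and the hemidesmosome list also without DN-Clim replicate 2. Here and below, the 2 covariates and replicate 3 alone are not separate checks, since each covariate sets DN-Clim replicates 1 and 2 apart. The mean lens signal was 11.85 and 12.1 on them and 8.16 to 9.21 on the other arrays. Xist minus Y-linked genes was 5.565 and 4.065 on them and 6.731 to 7.79 on the others. The desmosome list (median -0.29, 21 genes, adjusted p = 0.000198, and 0.525 with an estimated correlation) held Cldn7 at -0.71 and Ocln at -0.49, and its array medians were -0.09, -0.67 and -0.18. The basal and limbal progenitor list (median -0.28, 21 genes, adjusted p = 0.00108, and 0.416 with an estimated correlation) held Igfbp5 at -1.34, the 1 gene that fell adjusted over the list alone, and its array medians were -0.20, -0.52 and -0.20. Both lost the call with array weights, the desmosome list also without DN-Clim replicate 2 and the basal list without DN-Clim replicate 3. The Wnt ligand list was lower (median -0.12, 23 genes, adjusted p = 0.0411, and 0.744 with an estimated correlation), with Wnt5a at -1.17. Its array medians were -0.19 and -0.45 on DN-Clim replicates 1 and 2 and 0.21 on replicate 3, and the call was kept in 8 of 19 refits. The list medians given for arrays are not corrected for the median of the whole array. That was 8.03, 7.95 and 8.21 on DN-Clim replicates 1, 2 and 3, and 8.11 to 8.17 in WT. Part of a small list median can therefore be an offset of the whole array. The Wnt target list (adjusted p = 0.0692) and the list of CLIM cofactors and LIM partners (adjusted p = 0.0692) did not pass.

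The lens and retina lists were higher in DN-Clim, with the high values on replicates 1 and 2. The lens list had a median of 1.89 over 20 genes, all above 0 (adjusted p = 1.17e-14, and 0.342 with an estimated correlation), and 0 members passed, also adjusted over the list alone. Relative to the WT mean its medians were 3.81 and 4.21 on DN-Clim replicates 1 and 2 and -0.26 on replicate 3. Cryab, a small heat shock protein of lens and other tissues, differed by 0.94 and Lim2, a lens fibre membrane protein, by 1.48. The retina and photoreceptor list had a median of 1.06 over 15 genes (adjusted p = 1.25e-11, and 0.342 with an estimated correlation), with 0 members passing, Pde6b at 1.36 and Six6 at 1.32. The cell cycle list was higher, with 33 of 35 genes above 0, a median of 0.33 (adjusted p = 1.25e-11, and 0.342 with an estimated correlation) and 0 members past the threshold. Plk1 differed by 0.81 and Cenpf by 0.66. Its array medians were 0.27 and 0.68 on DN-Clim replicates 1 and 2 and 0.06 on replicate 3, so that it was high on the arrays with the lens signal. The cell cycle and retina lists lost the call with the lens covariate and with replicate 3 alone, and the cell cycle list also with the sex covariate. The lens list turned to lower with replicate 3 alone. On WT replicate 3 the lens and retina medians were 0.32 and 0.47, against -0.19 and -0.51 on WT replicate 1 and -0.16 and -0.07 on WT replicate 2.

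The other lists that passed as lower were matrix proteases and inhibitors (median -0.19, Timp1 at -0.79), conjunctival markers (-0.20, Krt7 at -0.63), lymphatic and angiogenic genes (-0.26, Aplnr at -1.36), interferon response genes (-0.13, Ifih1 at -0.62), hair follicle stem cell genes (-0.23, Cd34 at -1.65) and ribosomal proteins (-0.13, Rplp1 at -0.31). Those that passed as higher were eye field transcription factors (0.34, Mab21l2 at 1.20), glycolysis (0.17, Ldha at 0.55), skeletal muscle (0.09, Mylpf at 1.68) and Notch signalling (0.14, Notch1 at 0.49). On DN-Clim replicates 1, 2 and 3 the array medians were 0.43, 0.49 and 0.05 for eye field factors and 0.23, 0.56 and 0.05 for glycolysis, and both lists lost the call with the lens covariate and with replicate 3 alone. For muscle they were 0.05, -0.27 and 0.42, and the call was lost without DN-Clim replicate 3. No member of these 10 lists passed over all genes, and the estimated correlation gave adjusted p-values from 0.342 to 0.716. The call was kept in 7 of 18 refits for interferon response, and of 19 refits in 8 for Notch signalling, 9 for hair follicle stem cell genes and 10 for lymphatic genes. It was kept in 13 for conjunctival markers, 14 for ribosomal proteins and 15 for matrix proteases. The matrix protease medians on DN-Clim replicates 1, 2 and 3 were -0.19, -0.53 and 0.02. That list lost its call with either covariate, without DN-Clim replicate 2 and with replicate 3 alone. The remaining 19 lists had camera adjusted p-values from 0.061 to 0.964. Among these the test, the mean and the median differed in sign for Wnt receptors, corneal endothelium, pigment cells, nerve, and oxidative genes.

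**Figure D2:**
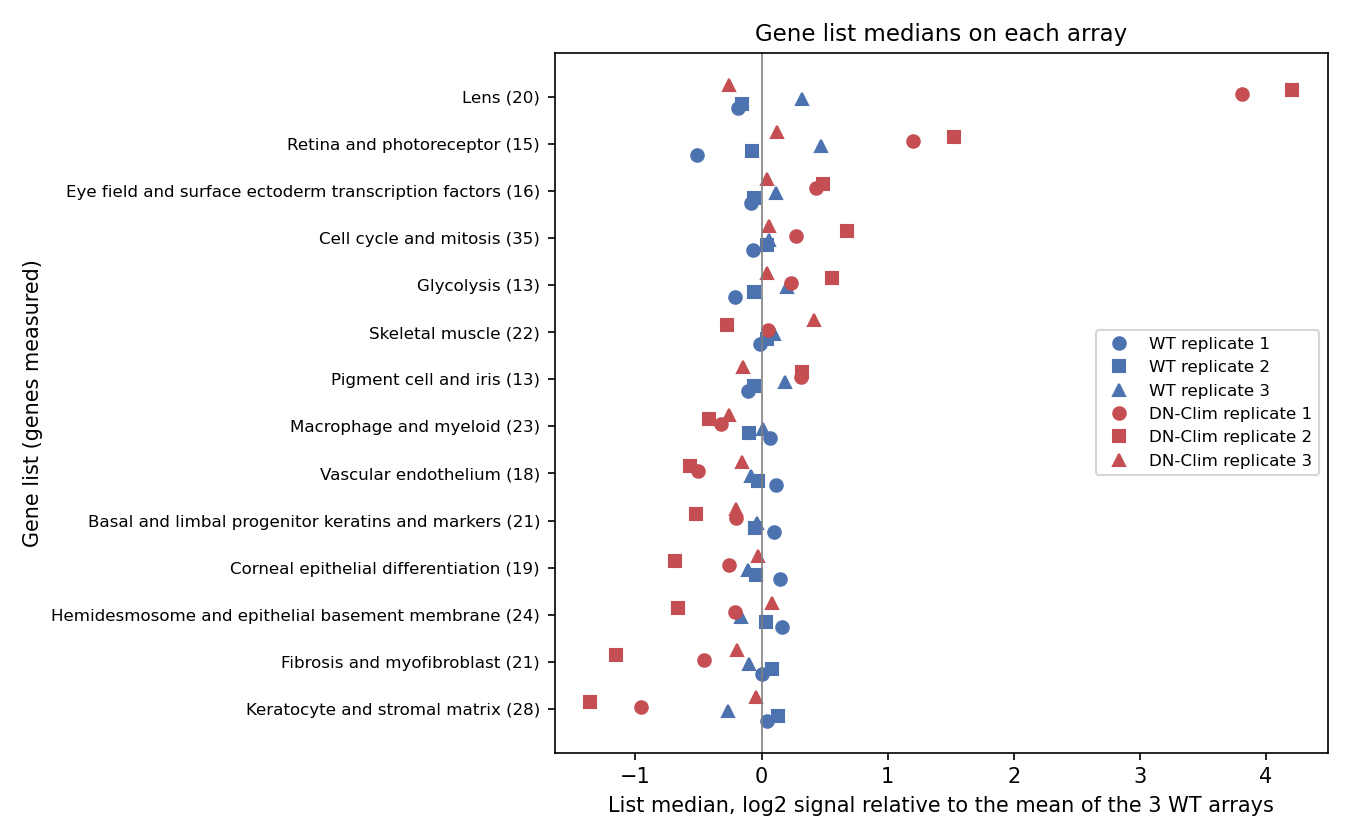
Points give the median over each gene list on each array, as log2 signal relative to the mean of the 3 WT arrays, and the numbers in brackets count the genes measured. DN-Clim replicates 1 and 2 lie apart from the other arrays for the lens list (3.81 and 4.21) and for the keratocyte list (-0.96 and -1.36), while DN-Clim replicate 3 lies at -0.26 and -0.04.

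Without the array labelled DN-Clim replicate 3, 128 probe sets rose and 355 fell in the remaining 2 DN-Clim samples against 3 WT. None of the other fits that left out a single array gave a probe set past the threshold. The p-values here do not account for the choice of the array left out. The 12 largest increases were all crystallins, the structural proteins of the lens. Crygs rose by 5.46 (SE 0.199, limma adjusted p = 3.37e-05), Crybb1 by 5.36 (SE 0.338, adjusted p = 0.000747) and Cryaa by 4.92 (SE 0.233, adjusted p = 0.000102). Of 20 lens genes 14 rose, and 17 did so adjusted over the list alone (camera adjusted p = 1.66e-33, and 0.429 with an estimated correlation). In this fit lens was the 1 list that passed the directional fry test (adjusted p = 0.0225). The keratocyte list moved the other way. Of 28 keratocyte genes 11 fell and 2 rose, and 23 fell and 2 rose adjusted over the list alone (camera adjusted p = 7.26e-11, and 0.429 with an estimated correlation). Pdgfra, a growth factor receptor of mesenchymal cells, fell by 2.17 (SE 0.203), as did Col3a1 (-1.92), Thbs2 (-1.88) and the sulfotransferase Chst5 (-1.84). Aldh1a1 rose by 1.44.

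Among the 12 largest decreases in the same 5 arrays was Hmcn1, a large basement membrane protein (-3.02). Tnmd fell by 2.88, Aspn fell by 2.73, Srpx fell by 2.49, and Ptgs2, the inducible cyclooxygenase, fell by 2.26. Of the fibrosis list 5 of 21 fell, among them Postn (-2.12), Twist1 (-1.73) and Fn1 (-1.36), and 11 fell adjusted over the list alone (camera adjusted p = 0.000136, and 0.429 with an estimated correlation). Of the vascular list 3 of 18 fell, Emcn (-2.55), Cdh5 (-1.42) and Erg (-1.31), and 8 fell adjusted over the list alone (adjusted p = 6.07e-05, and 0.429 with an estimated correlation). Aldh3a1 fell by 1.62 and Krt14 fell by 0.81 (SE 0.159, adjusted p = 0.0471). Of the Wnt ligands 1 of 23 fell, Wnt5a (-1.66), and the list passed as lower (adjusted p = 0.00478, and 0.538 with an estimated correlation). The other 3 Wnt lists did not pass (adjusted p = 0.0888 for inhibitors, 0.0736 for targets and 0.502 for receptors). Of the secreted inhibitors 2 of 16 fell, Dkk2 (-1.96) and Sfrp2 (-1.15), of the targets 2 of 27, Twist1 and Apcdd1 (-1.40), and of the receptors 0 of 29. Adjusted over the list alone, 6 targets fell and 2 rose, while Axin2 and Lef1 differed by -0.11 and -0.25 and did not pass. In the cell cycle list Nusap1 and Plk1 rose by 1.03 and 1.02, and 10 rose adjusted over the list alone. These 5 arrays hold 2 DN-Clim samples, both of which carried the lens signal, and the median of all probe sets was -0.12.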

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

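Besides the settings of the report, 20 alternatives were planned and 2 were added after seeing the data. The 2 are the array labelled DN-Clim replicate 3 alone against WT, where that sample is assumed to vary like WT, and the mean lens signal as a covariate. The lens covariate gives no value for the lens list or its members, because it is built from them. Of the comparisons of 116 named genes with their alternatives, 1895 kept direction and side of the threshold, 190 became past the threshold, 21 lost it and 59 turned direction, 0 of the last past it. Only 3 genes passed with all 6 arrays, so most of the kept comparisons are of genes that passed in neither setting. Many of the 116 were named for passing without DN-Clim replicate 3. That fit is among the alternatives, so their passes in it were fixed by the choice of genes. Of the 22 gene lists, 319 comparisons were kept, 87 lost the call and 10 turned. The vascular, macrophage and fibrosis lists kept call and direction in all 19 refits with the preset correlation, and the keratocyte list in 18. All 4 lost it with an estimated correlation (adjusted p = 0.342 each) and with the directional fry test (adjusted p from 0.183 to 0.393). Unless said otherwise the cause was not tested. Detection calls were not used here, so the signal over background that limits dim genes is unknown.

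The number of probe sets past the threshold was 1 with quantile normalization, 0 over all probe sets of the table, and 5, all lower, with a trended robust prior. With array weights, a fit that stopped before converging, it was 9004 (3289 higher and 5715 lower). It was 79 (6 higher and 73 lower) for DN-Clim replicate 3 alone. Leaving out single arrays gave 0 to 483 probe sets, 0 to 128 higher and 0 to 355 lower. The number of gene lists was 12 with a sex covariate, 13 for DN-Clim replicate 3 alone, 11 with the lens covariate, 0 with an estimated correlation, 0 with the directional fry test, and 12 to 23 when leaving out arrays. Without DN-Clim replicate 2 it was 12.

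Same-numbered arrays deviated from their group means with correlations of 0.017, -0.206 and -0.436, and no array correlated best with its own number. This gives no sign that the replicate number pairs the samples. It cannot exclude pairing, because deviations from the mean of so few arrays depend on each other. With the replicate number as a block, 9 probe sets passed, 9 of them lower, and 19 lists.

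Directions turned as follows, log2 DN-Clim minus WT. With the sex covariate Ldb2 was -0.17, Krt12 0.31, Col17a1 0.13, Axin2 0.10, Crygb -0.19, Cryga -0.36, Crygd -0.71, Cryba1 -0.62 and the Wnt ligand list mean 0.040. With median centring Krt12 was 0.041 and Axin2 0.034, with quantile normalization Axin2 was 0.019, and with array weights it was 0.080. Leaving out arrays, Ldb2 ran from -0.22 to 0.41, Krt12 from -0.31 to 0.14, Col17a1 from -0.47 to 0.036 and Axin2 from -0.11 to 0.10. With the lens covariate Ldb1 was -0.070, Ldb2 -0.41, Krt12 0.37, Col17a1 0.18, Axin2 0.077, Ccn1 0.081, Prox1 -0.15, Hmox1 -0.026, and the list means were 0.069 for Wnt ligands, -0.051 for conjunctiva and 0.0062 for glycolysis, each opposite in direction relative to other genes.

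With DN-Clim replicate 3 alone Ldb1 was -0.20, Ldb2 -0.58, Krt12 0.54, Col17a1 0.29 and Axin2 0.11. The crystallins were Crygs -1.09, Crybb1 -0.036, Cryba2 -0.086, Crybb3 -0.035, Cryaa -0.33, Cryba4 -1.44, Crygb -2.24, Crygc -1.81, Cryga -2.43, Crygd -2.88 and Cryba1 -2.46. Other genes were Srpx 0.073, Dkk2 0.020, Pdgfra 0.071, Thbs2 0.069, Chst5 0.29, Aqp1 0.20, Slc4a4 0.088, Fn1 0.052, Ccn1 0.35, Nusap1 -0.020, Erg 0.033, Prox1 -0.49, Rlbp1 -0.16, Pmp22 0.17 and Hmox1 -0.26. List means were 0.149 for Wnt ligands, 0.0165 for conjunctiva, 0.0413 for cell cycle, -0.675 for lens, -0.032 for glycolysis and -0.0458 for eye field factors. These lists are given because they turned direction relative to other genes. The cell cycle mean itself kept its sign.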

Other observations

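The array labelled DN-Clim replicate 3 was also set alone against WT, with its spread taken from the WT arrays. Emcn, Ctla2a and Psca were low there too, which adds nothing, because they were chosen for being low on all DN-Clim arrays. The genes named next were singled out after their values were seen. Gpnmb and Dct, genes of pigment cells, differed by -2.32 and -2.34 (limma adjusted p = 0.0361 for both), and Rgs5, a pericyte gene, by -1.99 (adjusted p = 0.0404). Trdn and Tnnt3, of skeletal muscle, differed by 2.30 (adjusted p = 0.0361) and 2.18 (adjusted p = 0.0404). The skeletal muscle list had a median of 0.42 on this array, and 0.05 and -0.27 on DN-Clim replicates 1 and 2. Y-linked genes also differed among arrays. Eif2s3y read 7.16 and 9.46 on DN-Clim replicates 1 and 2 and between 4.30 and 6.20 on the other 4, while Xist read between 12.11 and 12.60 on all 6. These 2 arrays were also those with the lens signal, so the Y-linked and lens signals cannot be told apart in these samples. Xist was high beside Y-linked genes on DN-Clim replicate 2, as in a mix of RNA from both sexes, but this was not tested.

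Of the tests below, the splits of the arrays and the test on tissues around the cornea were set before their results were seen, and those on lens genes, the label, stromal genes, the vascular list on DN-Clim replicate 3, and Emcn, Ctla2a and Psca after. The last of these replaced a test on the 3 genes themselves, which decides nothing because they were chosen for being low. For the lens genes and the label, how a value is read was also changed after it was seen: a count at the bound is taken as undecided, and a count of lowered genes was added to the median. As first worded, the lens count spoke against lens tissue and the median for a wrong label, and both are now read as undecided. For the tissues around the cornea, the bound set beforehand was wrong to pool lists that moved in opposite directions, so meeting it decides nothing. The 10 splits of the 6 arrays into 3 against 3 are too few for a share under 0.05. The real split gave 3 probe sets and the highest other split 5, and 2 splits, the real one included, gave at least 3. The split with 5 set WT replicates 1 and 2 and DN-Clim replicate 3 against the rest, so it follows the structure of the lens signal. For gene lists the real split gave 22 and the highest other 18, so that 1 split reached the real count.

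Lens genes were high on DN-Clim replicates 1 and 2, and stromal genes low on the same arrays, and WT replicate 3 leaned the same way, with list medians of 0.32 for lens and -0.26 for keratocytes. Retina medians were also high on DN-Clim replicates 1 and 2, 1.20 and 1.53 against 0.12 on replicate 3, and pigment cell medians 0.31 and 0.32 against -0.14, so a candidate explanation is tissue of the lens, alone or with other eye tissue, although the labels' protocol describes removal of other tissue and a PCR check for it. Of 6 lens genes that are not crystallins, 3 were higher on both arrays than on the other 4, Bfsp1 (by 2.23), Lim2 (1.79) and Bfsp2 (1.42). Mip (0.30), Gja3 (-0.11) and Birc7 (0.13) were not. The exact 95% binomial interval of this share runs from 11.8% to 88.2%. With so few genes only all or none of them could have decided the test. The interval also treats genes of the same arrays as independent, and its bound is not the share expected without a lens signal. Mip, an abundant lens fibre protein, read 7.76 and 8.43 on DN-Clim replicates 1 and 2. Of the 20 measured lens genes 15 had a WT mean above the median WT signal, while 0 were in another list. Dilution of all corneal RNA by lens RNA was examined as the whole cause of the stromal values. The stromal median minus the epithelial median was -0.642 (bootstrap 95% interval over genes -1.13 to -0.319), where equal dilution would give 0. The interval treats genes of the same 2 DN-Clim arrays as independent and does not measure the spread between samples. Epithelial genes that the added tissue also expresses would fall less. Yet the keratins always named, Krt12, Krt5 and Krt14, differed by -0.31, -0.35 and -0.81 without DN-Clim replicate 3, against a stromal median of -1.1. The keratocyte list medians were -0.96 and -1.36 on DN-Clim replicates 1 and 2, against -0.26 and -0.69 for epithelial differentiation. These values argue against equal dilution as the whole cause of the stromal values on these 2 arrays. A share of dilution stays open. The origin of the lens signal, and an effect of the genotype, stay open.

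DN-Clim replicate 3 resembled WT more than its own group. Yet it correlated with each WT array (0.949 to 0.962) less than these did with each other (0.970 to 0.981). On the first principal component (55.8% of the variance) it lay at -43.3, against -27.5 to 0.58 for WT and 27.5 and 64.8 for DN-Clim replicates 1 and 2. On the second (17.6%) it lay at -36.9, on the side of DN-Clim replicates 1 and 2 (-10.6 and -4.87), against 11.9 to 26.9 for WT. If the array were a mislabelled WT cornea, genes low on DN-Clim replicates 1 and 2 would lie in the WT range on it. Their medians on it were -0.179, -0.28 and -0.342 when WT replicates 1, 2 and 3 were held out, against 0.0603, -0.000349 and -0.371 on the held-out array, so their mean of -0.267 is inside the WT range only through WT replicate 3. In the same genes more values lay below -1 on this array than on the held-out WT array in each of the 3 choices, 36 against 4, 76 against 28 and 68 against 12, while for genes high on replicates 1 and 2 the counts above 1 were 1 against 2, 1 against 0 and 4 against 75. A wrong label cannot be told apart from a DN-Clim cornea with no lens signal, and no biological explanation was tested.

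Emcn, Ctla2a and Psca fell in DN-Clim, and the vascular list passed as lower with the preset correlation (adjusted p = 0.342 with an estimated one), with Emcn its 1 passing member of 18. On DN-Clim replicate 3, dilution by lens RNA is argued against as the cause of the low values of the 3 genes. The lens list median of that array was -0.258 (bootstrap 95% interval over genes -1.27 to 0.0131), below the highest WT array at 0.319. A share of dilution on replicates 1 and 2 stays open. For the whole vascular list the median gap on DN-Clim replicate 3 to the lowest WT array, taken gene by gene, was -0.0275 (-0.294 to 0.196). An array like WT would mostly lie above that lowest value, so 0 is too strict a bound and the gap decides nothing. Relative to the WT mean, the list median was -0.16 on DN-Clim replicate 3 and -0.08 to 0.11 on the WT arrays. A lower vessel content was not tested. Less tissue from around the cornea stays open: the pooled median of 4 lists of such tissues was -0.0304 (-0.111 to 0.0292) against -0.431 for the vascular list, but the 4 did not move together. Conjunctiva passed as lower (median -0.199, adjusted p = 0.0156, and 0.655 with an estimated correlation), at -0.28, -0.51 and 0.25 on DN-Clim replicates 1, 2 and 3, muscle as higher (0.0932, adjusted p = 0.0203, and 0.716), and pigment cells (0.00682) and nerve (-0.0154) did not pass.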
